A study of Rattus norvegicus with 24 samples.

How the data were processed

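Poly(A)-selected, strand-specific RNA libraries were made from hippocampus and amygdala of male rats and sequenced as paired ends, per the labels' protocols. The submitters' processing notes name STAR and DESeq2 without a role or version. The genome build, the annotation, the counting tool and the filter applied before deposit are not given in the sources used here.

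The authors deposited 1 table per region, with genes in rows. Per its file header, the amygdala table gives a gene name. Each table also has a column of Ensembl gene identifiers, which was recognized from its values. Each table has 12 value columns with generic names that match no sample label, and these 24 columns were used in no step. All tests planned before the data were examined needed an age or a diet for each column, and were therefore not run. They comprised age, diet and interaction contrasts, differences of age or diet effects between the regions, and tests of gene lists. The other settings chosen for them and the rule for naming genes from a comparison were not used either.

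From the identifier and name columns, a Python 3.11.15 script counted the genes listed in each table and the identifiers shared by both, by exact match. The 42 gene lists, fixed before the data were examined, were matched to the amygdala table's gene names without regard to case, and a matched gene was called listed for the hippocampus when any of its identifiers was in that table. Among the amygdala gene names, 103 were carried by more than 1 identifier. Genes were not given coordinates. Sequencing depth and its precision are not reported, since they belong to the columns that were not used.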

Results

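Messenger RNA was sequenced from the hippocampus and the amygdala, brain regions involved in memory and in emotional learning, of male rats of the F344 X BN cross. Per the labels, the 24 samples fell into 8 groups of 3: young or aged animals, on chow or on a high-fat diet (HFD), in each of the 2 regions. The design asks how age, diet and their combination relate to gene expression within each region. The labels number the samples within a group but do not say whether the hippocampus and amygdala samples came from the same animals.

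No effect of age or diet is reported here, and no expression level, fold change or p-value is given for any gene. The measurements were held in 2 tables, 1 per region, whose 12 value columns each carried generic names. None of these names (0 of 24) occurred in the label of any sample, so no column could be assigned to an animal, an age or a diet. Column order was not used in place of a label, because a wrong assignment would give false age and diet effects. The depth of each sample is not reported for the same reason. What follows describes which genes were listed for each region in the rows used here, which depends on the filter applied before deposit and does not measure expression.

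The hippocampus table listed 20469 genes by Ensembl identifier and the amygdala table listed 16871. Of these, 16389 were listed in both, which is 97.1% of the amygdala genes and 80.1% of the hippocampus genes. A further 4080 genes were listed for the hippocampus alone and 482 for the amygdala alone. No test was applied to these counts, since each region has a single list of genes, without replicate lists.

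Gene names came from the amygdala table, which named 14239 of its 16871 genes and left 2632 blank. Genes listed for the hippocampus alone therefore had no name here. Of the 842 distinct symbols in the 42 gene lists fixed before the data were examined, 618 were named in the amygdala table, and 602 of those were also listed for the hippocampus by the same identifier.

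Among markers of glia, 16 of 22 microglial genes were named in the amygdala table and all 16 were also listed for the hippocampus. Of 16 astrocyte genes, 13 were named and 12 were listed in both regions. Of 21 oligodendrocyte and myelin genes, 16 were named and 16 were listed in both. Among neuronal markers, 13 of 15 excitatory genes were named and listed in both regions, as were 13 of the 14 inhibitory genes named out of 17.

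Lists bearing on diet and immune function were covered to different degrees. Of 29 genes of fatty acid oxidation and PPAR targets, 23 were named and 21 listed in both regions. Of 30 genes of cholesterol and fatty acid synthesis, 24 were named and 23 listed in both. The cytokine, inflammasome and toll-like receptor list had 28 of its 32 genes named, each also listed for the hippocampus, and the complement list had 17 of 22. By contrast, 1 of 12 MHC class II genes, 1 of 21 genes of MHC class I and antigen processing and 0 of 13 mitochondrially encoded genes were matched by name. A symbol that was not matched can be a gene outside the rows used here, a gene with a blank name or a gene under another name, and these were not told apart.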

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

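No paired analysis was possible because value columns carry no sample name or replicate number. The planned tests between age or diet groups were unpaired. They were not run because no column could be assigned to an age or a diet. The other settings chosen for those tests before the data were examined (another scaling, no filter, DESeq2, fits on fewer groups, omission of single libraries, other tests of gene lists) were not run for the same reason. An unpaired test between the regions needs no age or diet for each column, but it was not among the planned tests and was not run. Both settings that follow were chosen after seeing the data. With case respected in the match, 618 list symbols were named in the amygdala table and 602 were also listed for the hippocampus, the same counts as without regard to case. With names carried by more than 1 identifier left out, the counts were 613 and 597.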

Other observations

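Among the 618 named list symbols, 16 were listed for the amygdala and not, under the same identifier, in the hippocampus rows used here. Over all 14239 named amygdala identifiers, 412 were listed for the amygdala alone. The 16 genes were chosen after the tables had been compared. They include Gfap, an intermediate filament of astrocytes, Gad2, an enzyme of GABA synthesis, and Prox1, a transcription factor of dentate granule neurons. Also among them are Vamp2, a synaptic vesicle protein, and the ribosomal protein gene Rps15. These are listings after a filter whose rule is not given in the sources used here. They are not evidence on the expression of these genes in the hippocampus, and no biological explanation was tested.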
